A study of Mus musculus with 10 samples.

How the data were processed

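Gastrocnemius muscle, the large calf muscle, from male mice aged 16 weeks was measured on 10 arrays, 5 from normal mice (control) and 5 from mdx mice, a strain whose dystrophin gene carries a mutation that stops translation early. The group of each array came from its title and description. The labels do not say that the arrays of a group came from separate animals, so the p-values measure the spread between these samples, which may be in part technical.

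The deposited values are probe set intensities on a linear scale, with no log taken. The software, the background correction and the scaling were not given in the sources used here. Tested on the values, the mean after trimming 2% from each end lay between 800.7 and 800.9 on 9 arrays and at 723.1 on mdx replicate 1, so that each array appears to have been scaled by 1 factor before deposit. Of the values on each array, 19.7% to 23.8% were below 0, which background subtraction gives. The share was lower in mdx, at a mean of 20.8% against 23.4% in control (exact permutation p = 0.00794). The labels name no batch, so a difference in array processing between the groups could not be told from genotype. Because each array was brought to about the same mean, these intensities measure a gene relative to the other genes of its array, and a change in total RNA per fibre cannot be seen. The number of arrays limits the precision.

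The table held 12488 probe sets, of which 66 were controls and were left out of the tests. Genes were named through the annotation of the array platform, with 10833 probe sets assigned to 1 gene, 396 to several and 1193 to none. No gene was named from a probe set with several. Symbols were looked up by gene number in the mouse reference gene table of assembly GRCm38.p6, which changed 0 of them. No coordinates were used. The probe sets named 8251 genes.

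The design fixed before the data were examined took the 20th percentile of all values as the pseudocount. That value came out at -13.8 here and could not serve. It was replaced, after the distribution of values had been seen and before any comparison of the groups, by a noise level of 156.8, the SD of noise estimated from the 27483 values below 0. Negative values were set to 0 and log2(intensity + 156.8) was taken. A fold change on this scale understates the change of dim genes. Where all 5 arrays of a group lay below the noise level, the fold is given as at least the brighter group's geometric mean, the mean on the log2 scale, over that level. The scaling was kept as deposited, because the largest deviation of a trimmed mean was 8.82%, within the tolerance of 10% fixed beforehand. A probe set was tested when its intensity was above 134.3, the 40th percentile of all values, on at least 5 of the 10 arrays, whatever their group. That left 7612 probe sets, of which 792 had no single gene, and 5767 genes.

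Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, two-sided), with Benjamini-Hochberg adjustment over the 7612 probe sets and a threshold of 0.05. Log2 changes are mdx minus control, with the standard error (SE) of the fit. For a gene with several probe sets, the brightest on average represents it, and only this probe set was ranked among the largest rises and falls. Of the other probe sets of the genes in the lists and of the named genes, 57 gave the same call as the representative, 42 were uncalled like it, 48 were uncalled where it was called, 10 were called where it was not, 4 were called in the opposite direction and 4 agreed in direction but lay over 2-fold apart.

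Before the data were examined, 32 gene lists were fixed, of pathways and of the cell types a muscle piece can hold. Each was tested with limma's camera, a competitive test against all other genes, at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 32 lists. Camera with an estimated correlation and fry, a rotation test of whether a list moves one way on balance, were run as alternatives. A further test was added after the camera results and the other splits of the arrays had been seen. In it, the mean of a list minus the median gene of the same array was compared between the groups by an exact permutation test, two-sided, adjusted over the 32 lists. The smallest p that 5 arrays against 5 can give there is 0.00794.

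The named genes were chosen by a rule fixed beforehand. It took the dystrophin and utrophin genes, the 10 largest rises and 10 largest falls among called probe sets with 1 gene and with no overlap between the groups, and up to 4 members of each list with the smallest p. The script was tested on data simulated for 7612 probe sets with the spread of these arrays. It recovered 37.3% of changes of 0.5 on the log2 scale, 80.6% of changes of 1 and 97.0% of changes of 2. Only 67, 67 and 66 probe sets were given these changes, a far smaller share than the 33.1% called in the data. The adjusted threshold depends on that share, so these rates do not carry over to the data. In that test 4.67% of the calls were false, and 0 calls were made with no change simulated.

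Alternatives fixed beforehand were quantile normalization, median centring, other pseudocounts, a floor, other filters, other variance models, array weights, the replicate number as a block, each array left out in turn, a 2-fold threshold and other set tests. Alternatives added after seeing the data were equal trimmed means, scaling to the hybridization controls, and leaving out mdx replicates 1 and 5 together.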

Results

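Transcript levels in gastrocnemius muscle of 16-week-old male mdx mice, which lack functional dystrophin, were compared with those of normal mice of the same age and sex on 5 arrays per group. The comparison asks which transcripts differ in muscle that has been through degeneration and regeneration. Arrays of one group resembled each other more than arrays of different groups, with correlations across probe sets of 0.946 to 0.967 within control, 0.934 to 0.968 within mdx and 0.860 to 0.892 between the groups. The first principal component held 51.6% of the variance and separated the groups, and the next held 9.47% and set mdx replicate 5 apart. The ratio of the 3' to the 5' probe set of actin, a measure of RNA quality, was lower in mdx, at 1.02 ± 0.048 against 1.13 ± 0.038 (exact permutation p = 0.0159), and that of Gapdh was 0.732 against 0.735 (p = 0.921).

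**Figure D1:**
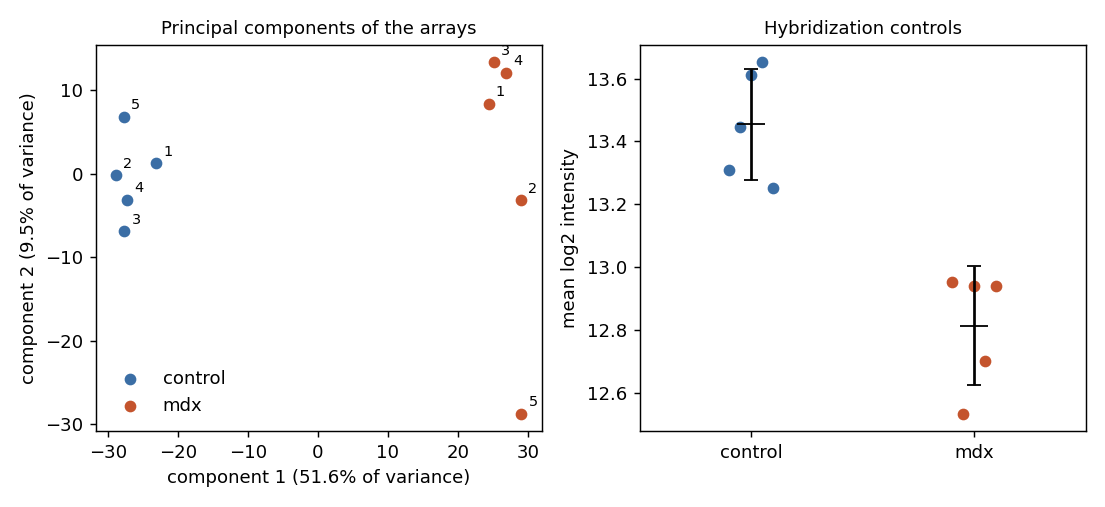
Left, the 10 arrays on the first 2 principal components of the tested probe sets, numbered by replicate. Right, the mean log2 intensity of the hybridization controls on each array, with the group mean and SD (n = 5), which was 13.46 in control and 12.82 in mdx.

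The dystrophin transcript was lower in mdx muscle. Dmd, on chromosome X, which encodes the protein that links the fibre's cytoskeleton to its membrane, gave an intensity of 797 ± 147 in control and 188 ± 33.7 in mdx (SD, n = 5), a log2 change of -1.46 (SE 0.14, limma adjusted p = 6.17e-06). The mutation in this strain leaves most of the transcript sequence in place, so a lower level does not by itself check the genotype. Utrn, on chromosome 10, which encodes the dystrophin relative utrophin, did not pass the test with either of its probe sets, with log2 changes of -0.44 (adjusted p = 0.188) and 0.35 (adjusted p = 0.194). Of 13 tested genes of the dystrophin-associated proteins, 2 rose, 4 fell and 7 did not pass, or 2 and 5 adjusted over the list alone. Itga7 and Cav3, counted as not passing, each had another probe set called higher, at 0.66 and 0.41. Aqp4, counted as a fall, had another that did not pass, at -0.34. The laminin chain Lama2 rose by 0.57, and the muscle calpain Capn3 and the sarcoglycan Sgca fell by 0.40 and 0.43, both with a change of sign under scaling to the hybridization controls. The list had a median of 0.10 and a mean of -0.14, and camera gave an adjusted p of 0.797, while the exact test against the median gene of each array gave -0.20 (adjusted p = 0.0115). Dmd itself, at -1.46, counts among these 13 genes and the 4 that fell, and changed the most. The list values include it and were not computed without it.

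A large part of the transcriptome differed. Of 7612 probe sets tested, 2520 (33.1%) changed at an adjusted p below 0.05 by limma, 1191 higher and 1329 lower in mdx. Among the 583 that also changed at least 2-fold, 445 were higher and 138 lower. The calls covered 1973 genes, 915 higher and 1058 lower. The groups did not overlap at all for 25.1% of the tested probe sets, against 0.794% by chance for 5 arrays against 5.

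With each gene ranked by its brightest probe set, the 10 largest rises included 4 genes of the macrophage list, Lgals3, Tyrobp, Lyz2 and C1qc. Lgals3, the galactose-binding lectin made by activated macrophages, was below the noise level on all control arrays and at 9636 ± 1515 in mdx, at least 60.8-fold higher (log2 change 5.53, SE 0.17, adjusted p = 4.02e-09). Postn, the matrix protein periostin, went from 377 ± 137 to 10063 ± 1304, a log2 change of 4.28. The chemokine Ccl8 rose by 4.10, the class II antigen-presenting chain H2-Aa by 4.09, the lysosomal protease Ctss by 3.92 and the myeloid signalling adaptor Tyrobp by 3.79. Igf2, a growth factor of fetal and regenerating muscle, rose by 3.73, from 365 ± 111 to 6699 ± 832. Lyz2, the lysozyme of macrophages, rose by 3.58, although its near-identical relative Lyz1 could add to its signal. The complement chain C1qc rose by 3.53, and the leukocyte tetraspanin Cd53 was at least 10.8-fold higher. Dimmer probe sets that were left out of the ranking rose by as much for Myl4 (3.75), C1qb (3.60, against 0.09 and no call for its brightest) and Mmp12 (3.39).

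The 10 largest falls, ranked in the same way, were of mixed kinds. The carboxylesterase Ces1d was below the noise level in mdx and at least 4.65-fold lower (log2 change -2.47, SE 0.18, adjusted p = 7.29e-07). Csrp3, a muscle LIM protein of the sarcomere's Z-disc, fell by 2.22, from 8617 ± 2543 to 1675 ± 210. Mstn, or myostatin, the muscle-made inhibitor of muscle growth, fell by 1.93, from 3244 ± 352 to 744 ± 164. The slow myosin light chain Myl3 fell by 1.89, from 15032 ± 906 to 3974 ± 580. Hspa1a, an inducible heat shock protein with a near-identical copy, Hspa1b, fell by 2.11, and Hspa1b by 1.38. Oxt, the oxytocin gene, fell by 2.15, the DNA repair gene Fancc by 2.14, Eepd1 by 2.10, the seryl-tRNA synthetase gene Sars by 2.06, and the adenylyl cyclase Adcy2 was at least 3.11-fold lower. In mdx the mean intensities of Oxt, Fancc and Sars were 175, 162 and 83.5, near or below the noise level of 157, with 2, 3 and 2 of the 5 arrays below it. A dimmer probe set of the immunoglobulin gene Ighm, left out of the ranking, fell by 2.24, from 5250 ± 1453 to 981 ± 217. For Postn, H2-Aa, Eepd1 and Myl3, 1 array of a group stood apart from the other 4, and leaving out any single array ended none of these calls.

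**Figure D2:**
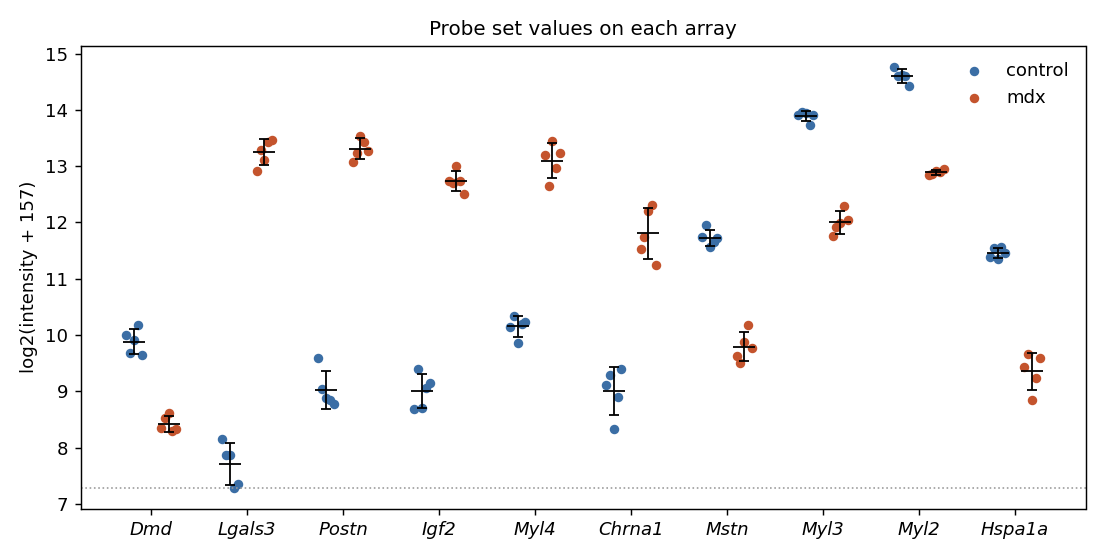
Log2(intensity + 157) of 10 named genes on each array, 5 control and 5 mdx, with the group mean and SD. The dotted line marks an intensity of 0. The groups do not overlap for any of the 10 genes, with log2 changes from 5.53 for Lgals3 to -2.11 for Hspa1a.

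Matrix genes rose together. Of 32 tested genes of fibrillar collagens and interstitial matrix, 25 rose, 2 fell and 5 did not pass, the same counts as adjusted over the list alone, with a median log2 change of 1.15 (camera adjusted p = 1.55e-15). Beside Postn, the collagen chains Col5a2 and Col6a3 rose by 2.24 and 2.02, and Sparc, a collagen-binding glycoprotein, by 1.39. Of 12 basement membrane genes 8 rose and 0 fell, here and adjusted over the list alone, with a median of 0.49 (camera adjusted p = 0.00108). Among them were Col15a1 (1.88), the laminin chains Lamb1 (0.75) and Lamc1 (0.55), and the linker Nid1 (0.99). Of 20 proteases and inhibitors 11 rose and 2 fell, or 12 and 2 adjusted over the list alone, with a median of 0.59 (camera adjusted p = 0.000214). The macrophage elastase Mmp12 was at least 12.9-fold higher, stromelysin Mmp3 at least 6.81-fold higher, and the inhibitor Timp1 rose by 2.04. The fibroblast markers moved with them. Of 14, 10 rose and 2 fell, here and adjusted over the list alone, with a median of 1.07 (camera adjusted p = 2.27e-06), but 9 of the 14 also stand in other lists and the call was lost when shared genes were left out. Lum, a collagen-binding proteoglycan, rose by 1.75, Mfap5, a microfibril protein, by 1.14, and the collagen chain Col1a1 by 1.47. The other probe sets of Mfap5 and Col1a1 did not pass, at 0.32 and 0.39. Cxcl12, counted as a rise at 0.35 here and among the chemokines below, had other probe sets called lower, at -0.41 and -0.50. Dcn, from 31123 to 24461, was among the falls (-0.35).

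Genes of macrophages, lysosomes and antigen presentation rose. Of 26 monocyte and macrophage markers 22 rose and 0 fell, here and adjusted over the list alone, with the highest median of the lists, 1.98 (camera adjusted p = 6.87e-17). Mpeg1, a pore-forming protein of macrophages, went from 490 ± 140 to 4774 ± 880, a log2 change of 2.94. Of 22 lysosomal genes 18 rose and 1 fell, or 19 and 1 adjusted over the list alone, with a median of 1.08 (camera adjusted p = 7.07e-13), among them the protease Lgmn (1.99) and the cathepsins Ctsb (1.54) and Ctsl (1.12). Of 18 antigen presentation genes 13 rose and 0 fell, here and adjusted over the list alone, with a median of 1.07 (camera adjusted p = 1.25e-09). The class II invariant chain Cd74 rose by 2.93 and the immunoproteasome subunit Psmb8 by 1.55, and Psmb9 was at least 2.42-fold higher. Of 17 chemokines and receptors 9 rose and 0 fell, or 10 and 0 adjusted over the list alone, with a median of 0.38 (camera adjusted p = 4.39e-06). This median stood at 0.66 with equal trimmed means and at 0.74 without control replicate 1, and ranged from 0.31 to 2.16 over the alternatives. Ccl9 rose by 3.11, Ccl6 by 2.31, and Ccr2, the receptor that draws monocytes into tissue, was at least 6.65-fold higher.

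Interferon and complement genes also rose, and lymphocyte markers were mixed. Of 21 interferon response genes 11 rose and 0 fell, or 12 and 0 adjusted over the list alone, with a median of 0.45 (camera adjusted p = 2.83e-05), among them Ifi204 (1.66), Ifitm3 (1.20) and Irgm2 (1.05), although other probe sets of Ifi204 and Ly6e did not pass. Of 13 complement genes 9 rose and 1 fell, here and adjusted over the list alone, with a median of 0.75 (camera adjusted p = 3.2e-05), and this call was lost with an adjusted p = 0.079 with an estimated correlation. C1qa rose by 2.66 and the inhibitor Serping1 by 1.28, and Cfp, properdin, was at least 5.83-fold higher. Of 13 lymphocyte markers 2 rose and 3 fell, here and adjusted over the list alone (camera adjusted p = 0.99), with a median of -0.06 against an upward sign in camera. The immunoglobulin joining chain Jchain rose by 0.63 and the T cell coreceptor Cd4 went from 453 ± 350 to -21.9 ± 160, below the noise level on 4 of 5 mdx arrays (log2 change -1.46), and the probe sets of Ighm ranged from -2.24 to 0.69. Of 10 granulocyte and mast cell markers 2 rose, both of mast cells, Cma1 (1.72) and Cpa3 (at least 1.93-fold), with 0 falling, here and adjusted over the list alone (camera adjusted p = 0.161, exact test 0.27, adjusted p = 0.047).

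Muscle genes of early development rose as a list, though not all of them. Of 24 embryonic and neonatal muscle genes 13 rose, 4 fell and 7 did not pass, or 14 and 4 adjusted over the list alone, with a median of 0.94 (camera adjusted p = 0.000172). The embryonic myosin light chain Myl4 went from 990 ± 136 to 8759 ± 1813, a log2 change of 2.94, the stress-induced ankyrin repeat protein Ankrd1 rose by 2.84 and the imprinted Peg3 by 2.20. Csrp3 was among the 4 that fell. Outside the rule for named genes, the neonatal myosin heavy chain Myh8 did not pass with either probe set, at -0.08 and -0.24. Chrna1, the acetylcholine receptor subunit that muscle without innervation makes in excess, rose by 2.80, from 374 ± 140 to 3572 ± 1146. Of 31 myogenic regulators and satellite cell genes 9 rose, 7 fell and 15 did not pass, or 11 and 7 adjusted over the list alone (camera adjusted p = 0.178, median 0.12, exact test 0.27, adjusted p = 0.0115), with rises of the helix-loop-helix inhibitor Id2 (2.07) and the intermediate filament Nes (1.22). Of 30 genes of the TGF-beta and IGF families 5 rose and 2 fell, here and adjusted over the list alone (camera adjusted p = 0.239, median 0.01), with rises of Igf2, Fstl1 (1.51) and Tgfbi (1.29). Of 34 genes of actin and the non-muscle cytoskeleton 25 rose and 1 fell, or 26 and 1 adjusted over the list alone, with a median of 0.81 (camera adjusted p = 1.27e-14). The actin-binding Tmsb10 and Cfl1 rose by 3.32 and 2.68, S100a4 by 1.81 and the annexin Anxa1 by 1.68. Of 28 cell cycle genes 9 rose and 1 fell, here and adjusted over the list alone, with a median of 0.45 (camera adjusted p = 0.000622), and this call was lost at an adjusted p = 0.0576 with an estimated correlation. Ccnd3 and the cycle inhibitor Cdkn1a rose by 1.64 and 1.46, and Stmn1 was at least 2.30-fold higher.

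Slow fibre genes had the lowest median of the muscle lists. Of 15, 10 fell, 1 rose and 4 did not pass, or 10 and 2 adjusted over the list alone, with a median of -0.73 (camera adjusted p = 3.49e-05, but adjusted p = 0.0576 with an estimated correlation). Myl2, the slow regulatory light chain, went from 24787 ± 2024 to 7454 ± 221, a log2 change of -1.71, and the slow myosin heavy chain Myh7 fell by 1.66. Of 20 fast fibre genes 13 fell, 2 rose and 5 did not pass, or 15 and 2 adjusted over the list alone, with a median of -0.53 (camera adjusted p = 0.00349, but adjusted p = 0.426 with an estimated correlation) and of -0.039 after quantile normalization (adjusted p = 0.954). The fast troponin Tnni2 fell by 0.69 and the actinin Actn2 by 0.54, and Mybph, a myosin-binding protein, rose by 1.30. The fast myosin heavy chain Myh1 fell by 0.42, but stood at 0.06 after quantile normalization. Of 24 genes of calcium handling and excitation 12 fell and 3 rose, or 13 and 3 adjusted over the list alone, with a median of -0.43 (camera adjusted p = 0.0103, but adjusted p = 0.146 with an estimated correlation). The calcium release channel Ryr1 fell by 1.03 and the calcium channel Cacna1s by 0.72.

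Of 66 oxidative phosphorylation genes 51 fell, 2 rose and 13 did not pass, or 55 and 2 adjusted over the list alone, with a median of -0.50 (camera adjusted p = 1.12e-12, but adjusted p = 0.144 with an estimated correlation) and of -0.20 after quantile normalization. The complex I subunits Ndufb5 and Ndufa3 fell by 0.81 and 0.74 and cytochrome c, Cycs, by 0.65. Of 39 genes of the TCA cycle and fatty acid oxidation 32 fell and 2 rose, or 33 and 2 adjusted over the list alone, with a median of -0.56 (camera adjusted p = 5.95e-10, but adjusted p = 0.0576 with an estimated correlation) and of -0.40 after quantile normalization. Lpl, lipoprotein lipase, fell by 0.99, and the beta-oxidation enzymes Hadhb and Acadm by 0.75 and 0.74. Of 25 glycolysis and glycogen genes 18 fell and 3 rose, here and adjusted over the list alone, with a median of -0.58 (camera adjusted p = 9.84e-05, but adjusted p = 0.113 with an estimated correlation) and of -0.18 after quantile normalization (adjusted p = 0.0753). Hexokinase Hk2 went from 7951 ± 1080 to 2258 ± 254, a log2 change of -1.74, glycogenin Gyg fell by 0.96 and the glucose transporter Slc2a4 by 0.77. Of 33 genes of muscle protein breakdown 10 fell and 3 rose, or 12 and 3 adjusted over the list alone, with a median of -0.21 (camera adjusted p = 0.0217, but adjusted p = 0.426 with an estimated correlation), among them Psmd11 (-0.96), Ube2d3 (-1.02), Ube2b (-0.73) and Bnip3 (-0.71). Of 39 genes of heat shock and redox defence 7 rose and 16 fell, or 8 and 17 adjusted over the list alone (camera adjusted p = 0.144, but called with no filter, median -0.18, exact test -0.12, adjusted p = 0.0115), with rises of the peroxiredoxin Prdx4 (1.62) and thioredoxin Txn1 (0.74).

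Camera called none of 6 further lists of cell types in the main comparison, but the exact test against the median gene, described below, gave lower means for endothelial (-0.18, adjusted p = 0.0293), red blood cell (-0.65, adjusted p = 0.0293) and skin markers (-0.45, adjusted p = 0.0221). Of 12 endothelial markers 1 rose and 2 fell (median -0.04, camera adjusted p = 0.523), Cd34 at 0.44, Flt1 at -0.74 and Vwf at -0.75. Of 10 smooth muscle and pericyte markers 3 rose and 2 fell (median -0.0046, mean 0.10, camera adjusted p = 0.546), with Acta2, also a gene of immature fibres, at 1.30 and Myh11 at -0.55. Among 7 adipocyte markers 2 rose, Adipoq (0.76) and Cebpa (1.14), and 2 fell (median -0.15, mean 0.10, camera adjusted p = 0.891). Of 4 nerve and Schwann cell markers 0 rose and 1 fell (median -0.21, camera adjusted p = 0.309), Mbp, whose 2 probe sets were called in opposite directions, at -0.90 and 0.60, the first losing its call under 14 alternatives. Of 4 red blood cell markers the globin genes Hba-a1 and Hbb-b2 fell by 1.04 and 0.80 (list median -0.59, camera adjusted p = 0.0919), and camera called the list with the replicate number as a block (adjusted p = 0.0258), under scaling to the hybridization controls (adjusted p = 0.021) and without control replicate 1. Of 4 skin markers Sprr1b fell by 1.13 (list median -0.19, camera adjusted p = 0.278). Adjusted over the list alone, the counts of these 6 lists were the same except that 0 nerve markers fell.

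**Figure D3:**
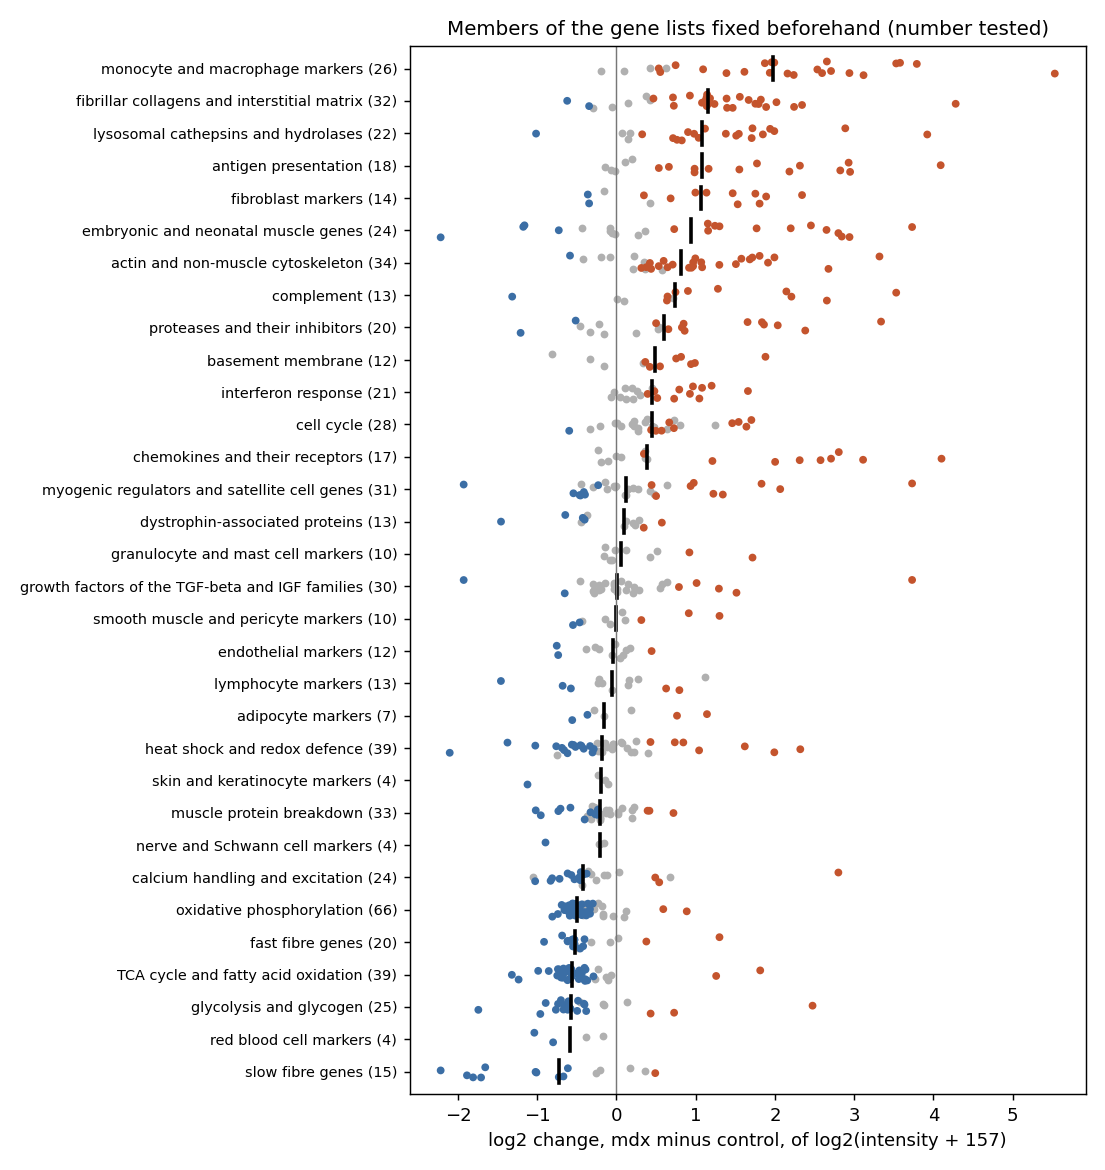
Log2 change, mdx minus control, of every tested member of the 32 gene lists, with the number tested. Orange points rose and blue points fell at an adjusted p below 0.05, grey points did not pass, and black bars mark the list medians, from 1.98 for macrophage markers to -0.73 for slow fibre genes. The bars of the falling lists other than slow fibre and red blood cell markers lie above 0 under scaling to the hybridization controls.

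Of the 32 lists, camera called 20, 13 higher and 7 lower, and 11 with an estimated correlation, all higher, so that none of the 7 falling lists held there. Fry called 27, adding the lists of granulocytes, myogenic regulators, TGF-beta and IGF families, heat shock, smooth muscle, red blood cells and skin. The count of 20 is not beyond what other groupings of the arrays gave. At the preset correlation 11 of 100 splits, the real one included, called as many lists. With an estimated correlation the highest of the other splits called 0. Neither result decides about chance, since the other splits mix the groups and keep part of their difference. In the exact permutation test of a list's mean against the median gene of each array, chosen after these results were seen, 27 of the 32 lists passed, 15 higher and 12 lower, 22 of them at an unadjusted p of 0.00794, the smallest possible. How many arbitrary gene sets would pass it was not tested. The median gene itself stood higher in mdx, which is part of the small lower results. Heat shock genes had a mean log2 change of -0.07 but -0.12 in this test, and endothelial markers -0.13 but -0.18.

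The direction of the falls depends on the scale. The hybridization controls, bacterial and phage transcripts that are usually added in fixed amounts, were lower on the mdx arrays, at log2 12.82 ± 0.19 against 13.46 ± 0.18 (SD, n = 5, exact permutation p = 0.00794). Scaling to them moved the median of all tested probe sets to 0.45 and gave 3536 probe sets higher and 126 lower, in place of 1191 and 1329. The medians of the lists of oxidative phosphorylation, TCA cycle and fatty acid oxidation, glycolysis and fast fibres then stood at 0.13, 0.07, 0.04 and 0.11, those of calcium handling and protein breakdown at 0.18 and 0.39, and that of slow fibre genes at -0.12. The camera calls of fast fibres, protein breakdown and cell cycle were lost there, as were those of fast fibres, glycolysis, calcium handling and protein breakdown after quantile normalization, and of the last 2 with a stricter filter. Of the genes named above, Capn3, Sgca, Actn2 and Myh1 turned sign under scaling to the hybridization controls, and the falls of Tnni2, Cacna1s, Ndufb5, Ndufa3, Cycs, Lpl, Hadhb, Acadm, Gyg, Slc2a4, Psmd11, Ube2d3, Ube2b, Bnip3, Flt1, Vwf, Myh11, Hba-a1, Hbb-b2 and the brightest probe set of Ighm (-0.68) no longer passed. The list mean minus the median gene of the same array was lower in mdx for the same lists, by differences of -0.47, -0.50, -0.42, -0.41, -0.28, -0.24 and -0.90 (exact permutation, adjusted p = 0.0293 for fast fibres and 0.0115 for each of the others). After quantile normalization the first 4 of these differences were -0.20, -0.34, -0.16 and -0.0078, with exact permutation p = 0.00794 for each of the first 3 and p = 0.865 for fast fibres.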

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

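All tests in this part were chosen after the results were seen, except the tests of other splits of the arrays, for the counts of probe sets and of lists at the preset correlation, and the rule for arrays that stand apart.

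Among 278 groups of 5 values, 19 had an array whose gap to its nearest neighbour was large against the range of the group, where chance gives about 13.9. Control replicate 1 was high for Postn (616), Eepd1 (6099), Cd4 (1056), Ighm (9531), Cd74 (2293) and Cdkn1a (684). Control replicate 3 was high for Ly6e (7575) and Actn2 (7608) and low for Psmb9 (-360). Control replicate 4 was low for Myl3 (13481) and high for Myh11 (902), and control replicate 2 was low for Il7r (10.9). Mdx replicate 1 was low for H2-Aa (8887) and Ighm (2910), mdx replicate 2 high for Lgmn (4158) and mdx replicate 4 high for Gyg (6770). Of whole arrays, mdx replicate 1 had a low trimmed mean (723.1) and a low median (241.2), and mdx replicate 5 a high root mean square deviation from its group (0.358). Outside the tested probe sets, the control probe set for the mouse B1 repeat was higher on every mdx array, at a mean of 21059 against 14337. The rule for these probe sets looked only for rises. The 3' control probe set of mouse pyruvate carboxylase was lower on every mdx array, at a mean of 358 against 1269. The brighter probe set for the B2 repeat had a lower mean in mdx, 26791 against 39775, with overlap between the groups.

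The counts of changed probe sets exceeded those of other groupings of the same arrays. Of 100 of the 126 possible splits, 1, the real one, gave as many changed probe sets (2520, highest other 3). No other split gave as many higher (1191, highest other 2) or as many lower (1329, highest other 2). Every other split mixes the groups, which puts part of their difference into the spread within its sides and lowers the calls. The real grouping thus ranked first, but these splits do not show what chance gives without a group difference. They cannot exclude a batch that runs with the groups. At the preset correlation 11 of the 100 splits, the real one included, called as many as the 20 gene lists, and the highest of the others called 21. Every other split keeps part of the difference between mdx and control. Chance is therefore not excluded for this count, nor do these splits measure it. With an estimated correlation the real split called 11 lists, 1 of the 100 splits called as many, and the highest other called 0. The group difference within the sides of the other splits can raise the estimated correlation there, so this 0 does not exclude chance.

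The lists of energy metabolism and fast fibres had medians of -0.50, -0.56, -0.58 and -0.53, a pattern picked after the medians of all lists had been seen. A factor per array cancels in the excess of each list over its array's median gene, so that the exact p of at most 0.0238 found there only restates the fall relative to other genes. Scaling that depends on intensity stays open, since after quantile normalization the largest p was 0.865, that of fast fibres, while the other 3 stood at 0.00794, and for the fall in absolute level scaling stays open too, since with the hybridization controls as the scale the lowest of the 4 medians was 0.0433. One lower share of fibre RNA could not be decided, since the 4 medians lay within 0.0829 of each other as deposited (bootstrap limits 0.0345 and 0.208), inside the bound of 0.3 set for it, but within 0.359 after quantile normalization (0.203 and 0.522), a condition added after those medians had been seen. Other lists of fibre genes, left out of this comparison, had medians of -0.21 (protein breakdown), -0.43 (calcium handling), -0.73 (slow fibres) and 0.10 (dystrophin-associated proteins).

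Slow fibre genes had lower values than fast ones, with means of -0.85 and -0.35 over 15 and 20 genes but medians of -0.73 and -0.53. The permutation p of 0.0364 restates this gap and treats genes as independent, while the fast genes had an estimated correlation of 0.531. Under one lower share of fibre RNA alone, both lists would move alike. Against the median gene of each array, slow genes changed by -0.90 (SD 0.10 in control, 0.06 in mdx) and fast ones by -0.41 (SD 0.22 and 0.17). The medians were -0.64 and -0.039 after quantile normalization, and -0.12 and 0.11 under scaling to the hybridization controls. For these lists, the values argue against one lower share as the whole cause. Less slow muscle in the mdx pieces stays possible and could not be decided, since 66.7% of the slow genes lay below the median of the fast ones, between the bounds set for either answer. A change of fibre type with the genotype remains untested.

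Macrophage markers rose more than endothelial, smooth muscle and nerve markers, with means 2.08 apart over 26 genes each (mean of the latter -0.08), and more than fibroblast markers, which rose too (14 genes, mean 0.965, permutation p = 0.0125). The permutation p of 1e-05, the smallest the permutations can give, with or without the fibroblast markers, only restates the gap that prompted it. A lower share of fibre RNA that raises all these cell types alike is argued against by the list means themselves. Against the median gene of each array, they changed by 1.95 for macrophage, -0.18 for endothelial, 0.05 for smooth muscle and -0.42 for nerve markers. Fibroblast markers rose by 0.91 there. More blood in the mdx pieces is argued against by Hba-a1, at -1.04, and Hbb-b2, at -0.80, although neither call held under scaling to the hybridization controls. More macrophages, or more of these transcripts per cell, may account for the rise as a hypothesis. The arrays do not separate these, and the permutations treat genes as independent.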

How the results depend on the processing

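Scaling to the hybridization controls, equal trimmed means and leaving out mdx replicates 1 and 5 together were alternatives chosen after seeing the data. Leaving out 1 array at a time gave 2241 to 2461 changed probe sets, 1072 to 1200 higher, 1156 to 1321 lower, a Dmd change of -1.52 to -1.38 and 20 to 21 lists. Dmd kept its direction and its call under every alternative run, from -2.08 with a floor to -1.01 with scaling to the hybridization controls. Requiring a 2-fold change left 583 probe sets, 445 higher and 138 lower, since it only adds a condition. Scaling to the hybridization controls gave 3536 higher and 126 lower, by its construction, since those controls were dimmer on mdx arrays. It also turned the sign of Capn3 (0.21), Sgca (0.20), Actn2 (0.077), Myh1 (0.22), Ogdh (0.013), Car3 (0.27), Scd1 (0.057), Pmp22 (0.45) and Des (0.16). Quantile normalization turned Myh1 (0.064) and Car3 (0.080), and the cause was not tested. An estimated correlation called 11 lists in place of 20. The lists that lost their call had estimates from 0.040 (cell cycle) to 0.531 (fast fibres), above the preset 0.01. Those that kept it had estimates from -0.078 (basement membrane) to 0.176 (macrophage markers), and nothing further was tested. Quantile normalization called 16, without fast fibres, glycolysis, calcium handling and protein breakdown. Over the single genes and all alternatives, 3065 results were the same, and 47 lost and 7 gained a call with their sign kept. A further 11 turned sign, and of these only Car3 and Pmp22 under scaling to the hybridization controls passed. Over the lists 866 were the same, 19 lost and 11 gained a call, and 0 were reversed. Mbp lost its call under 14 alternatives and Scd1 under 11, besides the scaling to the hybridization controls that turned the sign of Scd1. The replicate number as a block gave 2212 changed probe sets, 1078 higher and 1134 lower, with Dmd at -1.46 and 21 lists, red blood cell markers being added and no other call of a named gene or list changed. Arrays of the same number did not deviate together (correlations 0.01, 0.05, -0.05, -0.03 and -0.13, and 0 of 5 numbers matched best with their own), so the numbers were not taken to pair the samples. Probe sets near the noise level of 156.8 limit what can be called for dim genes.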

Other observations

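The 4 gene lists in this part were put together after the data had been seen, and all tests here were chosen then. Their genes lie mostly outside the rule for named genes.

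Several imprinted genes, which are active from only one parental copy and mostly high in fetal tissue, rose with Igf2. Of 19 tested, 8 rose, 3 fell and 8 did not pass. Peg3 rose by 2.20, Gatm by 1.78, Meg3 by 1.77, Mest by 1.57, Cdkn1c by 1.16 and Ndn by 0.60, while Gnas fell by 0.52. The hypothesis that imprinted genes move together in mdx passed with camera (adjusted p = 0.00893 among the fixed and added lists) but not with an estimated correlation (adjusted p = 0.0656), so it stays open. The list was put together after Igf2 and Peg3 had been seen to rise, which favours it.

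Of 13 circadian clock genes, 0 rose, 6 fell and 7 did not pass. Dbp fell by 1.42, Nr1d1 by 0.98, Tef by 0.54 and Nr1d2 by 0.53 (camera adjusted p = 0.0309, but adjusted p = 0.202 with an estimated correlation). A different time of day of collection may account for this, and would move Arntl and Npas2 opposite to Dbp, the Per genes and the Nr1d genes. Npas2 was not among the tested genes, so that the first arm rested on Arntl alone. Of these 2 arms 3 genes were called, all of the latter, while Arntl did not pass at 0.23 (adjusted p = 0.433), so that neither answer was reached. Collection times were not given in the sources used here.

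Cholesterol synthesis genes gave a negative result as a group. Of 10, 0 rose and 2 fell, Fdft1 by 1.55 and Sc5d by 0.50 (camera adjusted p = 0.463). Ribosomal protein genes gave the same, with 4 of 24 higher and 3 lower (camera adjusted p = 0.498).

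Some of the largest changes belonged to probe sets with no single gene. The probe set shared by Lyz1 and Lyz2 rose by 5.04, from 499 ± 326 to 19865 ± 3887, and a probe set without a listed gene rose by 4.32. The largest fall of all tested, -2.76, was of another probe set without a single gene. It was below the noise level on all mdx arrays and at least 6.21-fold lower.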
